A study of Mus musculus with 6 samples.

How the data were processed

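Total RNA from N2A mouse neuroblastoma cells treated with empty vector (3 samples) or with a short hairpin RNA against PTB (3 samples) was depleted of ribosomal RNA, labelled from 1 µg and hybridised to Affymetrix mouse exon 1.0 ST arrays, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, which call the replicates biological.

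The deposited values are linear gene-level intensity per transcript cluster, 1 column per array, as whole numbers from -616 to 23431. GCOS 1.3 is named in the submitters' processing notes. How probes were summarised into transcript clusters, how background was subtracted and whether arrays were scaled to each other are not given in the sources used here. Negative numbers show that some background was subtracted, and the arrays' totals and upper quartiles differ, so the deposited intensity values were not quantile-normalized. Between 3.54% and 7.02% of clusters on an array were at or below 0. Gene-level values cannot show changes in exon inclusion.

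Genes were named through the platform annotation. Of 17213 transcript clusters, 15146 had 1 gene symbol, 1278 had several and 789 had none, and only those with 1 symbol were named. Of these, 15088 matched the RefSeq gene table for GRCm38.p6 by Entrez identifier, and 0 symbols needed updating. The build behind the array's probes was not used here, so no coordinates are printed. For the 320 genes with several clusters, the cluster with the highest mean over all arrays stood for the gene, which left 14807 genes. In 1 such gene with a called cluster, the clusters differed in sign.

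Values below 0 were set to 0 and log2(signal + 16) was taken, with no further normalization and no filter on dim clusters. All differences are PTB shRNA minus empty vector on this scale, which understates the change of dim genes. Each cluster was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on all 6 arrays without a block, leaving 4 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all clusters at a threshold of 0.05. Standard errors are limma's moderated ones, and signals are means ± SD of 3 arrays. An exact test of 3 arrays against 3 cannot give a p under 0.1, so limma's moderated test carries the gene calls. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

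Before the data were examined, 24 gene lists with 645 entries were fixed, of which 515 were measured. They cover the PTB family and cofactors, hosts of PTB-regulated exons, pan-neuronal genes, sympathoadrenal and neuroblastoma lineage genes, the REST complex with small C-terminal domain phosphatases, tissue-restricted splicing regulators, SR proteins and hnRNPs, and nonsense-mediated decay factors. Further lists hold DNA replication and mitosis, interferon response, p53 target, unfolded protein and amino acid stress response, cholesterol synthesis, glycolysis, actin cytoskeleton and adhesion, immediate early, ribosomal protein, oxidative phosphorylation and replication-dependent histone genes. The last 5 hold fibroblast, glial, leukocyte, epithelial and muscle markers. Some genes belong to more than 1 list. Lists were compared with all other clusters by camera with a preset inter-gene correlation of 0.01, adjusted over the 24 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move 1 way on balance without comparing them with other genes, were run beside it. In camera with an estimated correlation the adjustment tied many lists, called and uncalled, at an adjusted p of 0.761. That value therefore does not rank lists against each other. Each list's median was also placed among 10000 random lists of the same size whose members lay within 100 ranks in mean signal, a comparison added after the data had been seen.

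Named genes were chosen by a rule fixed before the data were examined. Ptbp1, Ptbp2 and Ptbp3 were always named. Then came the 12 largest rises and 12 largest falls among clusters with 1 gene symbol, adjusted p under 0.05 and no overlap between the groups, skipping genes known only by a clone or predicted-gene number. From each list up to 4 members past the threshold with the largest absolute difference were named, or up to 2 where none passed. This gave 71 genes, and any other gene named, in the results or in the closing observations, was chosen after its values were seen.

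The alternatives were quantile normalization, centring each array on its median, pseudocounts of 1 and 50, leaving out the dimmest 30% or 50% of clusters, eBayes with trend and robust settings, array weights, the replicate number as a block and leaving out each array in turn. The fit was tested on simulated data with the real clusters' means and spread, 17213 clusters of which 200 were changed. All the changed clusters were brighter than the median cluster, so the simulation does not show what is recovered among dim ones. The fit recovered 0% of the changes of 0.5 and 39% of the changes of 1 log2 unit, with 4 false calls, and made 0 calls when nothing was changed. Of 200 random lists, 7 had a camera p under 0.05. Both truly changed lists were called, but each held only changed clusters of 1 direction, so that call was easy. The simulated clusters were drawn independently and without a shift by brightness, while the real lists' estimated correlation reached 0.831. The simulation therefore does not show how often camera calls real lists wrongly.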

Results

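RNA from N2A cells, a mouse neuroblastoma line that can take on neuron-like features, was measured on Affymetrix mouse exon arrays. The cells had received either an empty vector (3 arrays) or a short hairpin RNA against the polypyrimidine tract binding protein PTB (3 arrays). PTB, the product of Ptbp1, is an RNA-binding protein best known for repressing exons, many of them used in neurons. The labels call the samples of each group biological replicates and put the loss of PTB protein close to 80%. The values used here are gene-level signals of 17213 transcript clusters, of which 15146 carried 1 gene symbol, and they do not show which exons were included. Summed signal per array was 10651755, 11617719 and 12509077 with empty vector and 10440265, 9098056 and 10123948 with PTB shRNA, while the array medians lay between 183 and 206. The number of arrays, 3 per group, limits the precision of every difference given here.

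The comparison of PTB shRNA with empty vector asks which RNAs differ in level between cells with and without the hairpin against PTB. A control hairpin is absent from these samples, so PTB loss cannot be told apart from other effects of expressing a hairpin. Ptbp1 itself fell, from a signal of 3998 ± 539 to 1435 ± 472 (SD, n = 3 arrays per group), a log2 difference of -1.51 with a standard error of 0.25 (adjusted p = 0.0402, limma). Its signals were 3387, 4203 and 4404 on the empty vector arrays and 1307, 1040 and 1957 on the PTB shRNA arrays. Ptbp2, the neuronal paralog whose RNA PTB is known to keep low by promoting the skipping of an exon, rose from 1528 ± 97.9 to 2982 ± 262, or 0.96 ± 0.10 (log2, SE; adjusted p = 0.0288). Ptbp3, the remaining paralog, measured 2259 ± 127 and 1512 ± 175, a log2 difference of -0.58 that did not pass (adjusted p = 0.0543, and 0.0473 with each array centred on its median). Among the 7 measured members of the PTB family and its cofactors, 1 rose and 1 fell over all genes tested, and 1 rose and 2 fell when adjusted over the list alone. With any 1 array left out, the adjusted p ranged from 0.0536 to 0.132 for Ptbp1 and from 0.0536 to 0.112 for Ptbp2, so neither passed. A pseudocount of 1 in place of 16 also ended the Ptbp1 call (log2 difference -1.52, adjusted p = 0.0605).

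**Figure D1:**
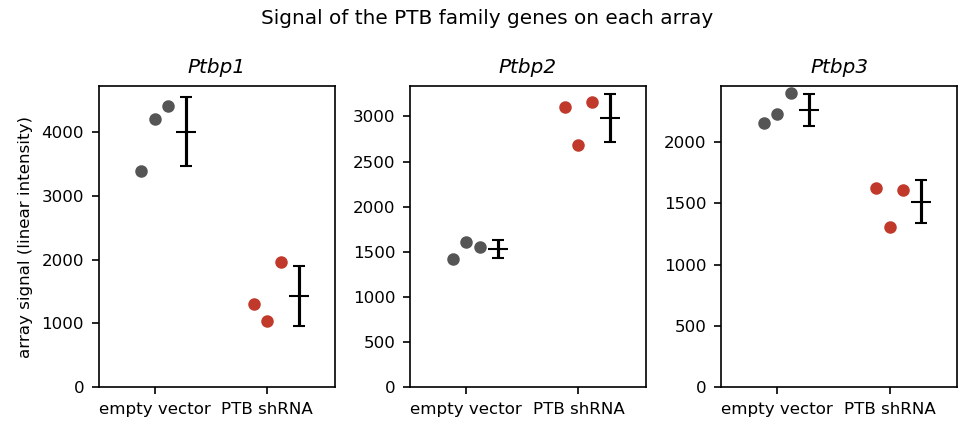
Signal (linear intensity, y axis) of Ptbp1, Ptbp2 and Ptbp3 on each of the 3 empty vector and 3 PTB shRNA arrays (points), with the mean and SD of each group (bars). For Ptbp1 the PTB shRNA arrays lay between 1040 and 1957 and the empty vector arrays between 3387 and 4404, while Ptbp2 ran the opposite way.

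Among the 12 largest rises, St18, a zinc-finger transcription factor, rose from 76 ± 21.7 to 450 ± 62.3, a log2 difference of 2.36 ± 0.20 (SE). Lmo3, a LIM-only transcriptional cofactor, rose by 2.29 ± 0.20, and Stmn4, a stathmin that acts on microtubules, by 2.19 ± 0.22. Nyap2, a neuronal phosphoprotein that binds phosphoinositide 3-kinase, rose by 2.15 ± 0.12, and Pik3r3, a regulatory subunit of that kinase, by 1.96 ± 0.16, from 475 ± 19.3 to 1918 ± 377. The adhesion G protein-coupled receptors Adgrf4 and Adgrg1 rose by 2.32 and 2.04, and the transmembrane adhesion protein Flrt3 by 1.84. Hsd17b13, a lipid-droplet protein, rose by 2.03, the growth factor genes Amh and Tgfb3 by 1.78 and 1.77, and the efflux transporter Abcg2 by 1.77. Their adjusted p-values lay between 0.0223 for St18 and 0.0320 for Amh. Signals with empty vector were only 4.3 ± 3.2 for Amh, 12.7 ± 6 for Flrt3 and 14.3 ± 2.1 for Hsd17b13, so the size and order of these rises depend on the pseudocount. With a pseudocount of 1 and of 50 the log2 difference was 3.50 and 0.94 for Amh, 2.75 and 1.11 for Flrt3 and 2.83 and 1.29 for Hsd17b13, against 2.58 and 1.99 for St18.

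The largest falls included Ankrd37, a gene known to be induced by low oxygen, which fell from 280 ± 111 to 46 ± 20, a log2 difference of -2.23 ± 0.40 (SE). The glycolytic enzyme gene Aldoc fell from 1366 ± 449 to 295 ± 74.9 (-2.12 ± 0.31), and the membrane-binding annexin Anxa2 from 601 ± 201 to 147 ± 27.6 (-1.88 ± 0.30). Pdia3, a disulfide isomerase of the endoplasmic reticulum, was the brightest of these genes and fell from 7086 ± 290 to 2551 ± 361 (-1.48 ± 0.13). Bok, of the BCL2 family, fell with a log2 difference of -1.58, as did the matrix gene Fbln2 (-1.54), the transcription factor gene Bhlhe40 (-1.54) and the gene of the heme-degrading enzyme Hmox1 (-1.54). Gtdc1 (-1.49), the ubiquitin ligase gene Rfwd3 (-1.47) and the early response gene Ier3 (-1.43) fell too. Adjusted p-values for these falls ran from 0.0223 for Pdia3 to 0.0456 for Bhlhe40, which was at 0.0549 after quantile normalization. With a pseudocount of 1, Ankrd37 (adjusted p = 0.0705), Aldoc (0.0536), Anxa2 (0.0557), Bhlhe40 (0.067) and Ier3 (0.0521) did not pass, nor did Amh among the rises (0.0505).

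**Figure D2:**
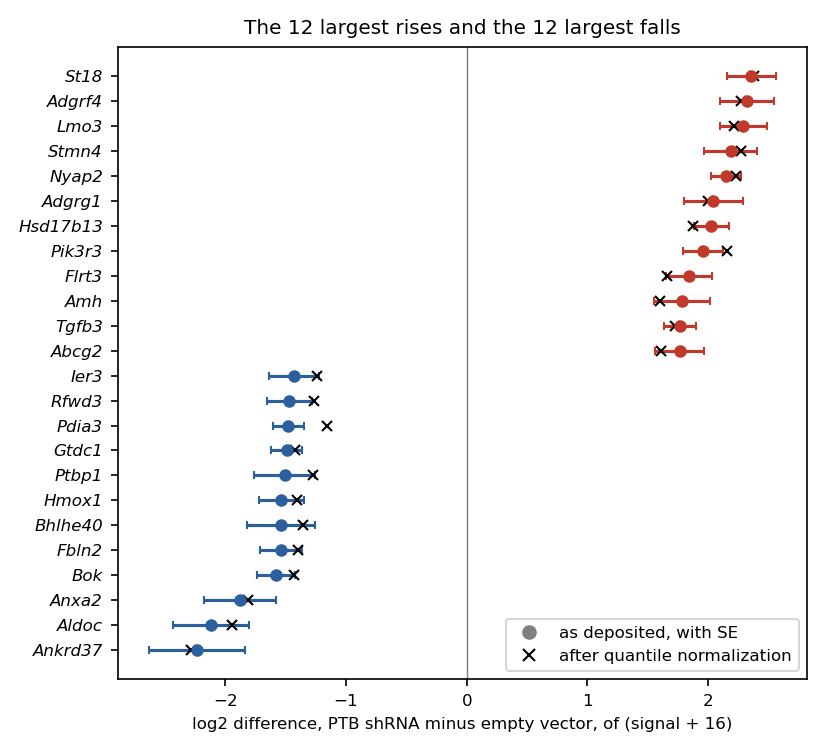
Log2 difference between PTB shRNA and empty vector (x axis) for the 12 largest rises and the 12 largest falls, with the standard error as bars and the value after quantile normalization as a cross. The rises ran from 1.77 (Abcg2) to 2.36 (St18) and the falls from -1.43 (Ier3) to -2.23 (Ankrd37), and no gene changed direction with the normalization.

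Over all transcript clusters, 234 were higher and 580 lower with PTB shRNA, so that 71.3% of the called clusters were lower. Counting 1 cluster per gene, 71 genes rose and 111 fell by at least 1 log2 unit. Quantile normalization of the arrays gave 506 higher and 491 lower (49.2% lower), with 205 of the higher and 399 of the lower clusters called both ways. The median log2 difference varied with signal brightness, with -0.24 in the brightest 10% of clusters and up to 0.22 among dimmer ones. Leaving out any 1 of the 6 arrays brought both limma counts to 0, with 1001 to 1721 clusters higher and 2008 to 3018 lower at an unadjusted threshold of 0.05. A pseudocount of 1 gave 84 higher and 132 lower, and 33 of the 52 named genes called besides Ptbp1 and Ptbp2 then did not pass.

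Genes of glucose metabolism had mostly lower signals with PTB shRNA. Of 18 measured glycolysis genes, 5 fell and none rose over all genes tested, and 14 fell when adjusted over the list alone. Besides Aldoc, the enzyme gene Eno2 fell from 1094 ± 269 to 406 ± 18, a log2 difference of -1.37, and Hk2 from 856 ± 194 to 329 ± 36.6 (-1.32). The lactate exporter gene Slc16a3 fell from 7604 ± 1163 to 3020.3 ± 518 (-1.33). The list's median log2 difference was -0.85 (camera adjusted p = 6.31e-07, and adjusted p = 0.761 with an estimated correlation). After quantile normalization the median was -0.54 and 5 members were called lower (camera adjusted p = 1.08e-05, and adjusted p = 0.484 with an estimated correlation). The positive members were Pfkm (0.08) and Ldhb (0.13), picked out after their values were seen. Among 32 measured oxidative phosphorylation genes, the complex I subunit gene Ndufv2 fell (-0.82 ± 0.15, SE), alone over all genes tested and as 1 of 6 when adjusted over the list alone. Their median was -0.24 and turned to 0.02 after quantile normalization, and the camera call (adjusted p = 0.0011, and adjusted p = 0.761 with an estimated correlation) ended there at 0.967. Of 18 measured cholesterol synthesis genes none passed over all genes tested and 4 fell when adjusted over the list alone. The lipid carrier gene Stard4 (-1.08, adjusted p = 0.0771, and 0.0479 with each array centred on its median) and the squalene synthase gene Fdft1 (-0.91, adjusted p = 0.0755) differed most. The median of that list was -0.33 (camera adjusted p = 0.0316, 0.581 after quantile normalization, and adjusted p = 0.761 with an estimated correlation). Its mean of -0.32 became -0.17 without empty vector array 3 (adjusted p = 0.255), and the list also did not pass without empty vector array 1 (0.098) or PTB shRNA array 2 (0.0869).

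Genes of growth and division also had mostly lower signals. All 44 measured DNA replication and mitosis genes had a negative difference, with a median of -0.49. Over all genes tested 2 fell, the mitotic kinase gene Aurka from 2114 ± 491 to 840 ± 213 (-1.32 ± 0.24, SE) and the spindle factor gene Tpx2 from 2963 ± 266 to 1845 ± 129 (-0.68 ± 0.11), and 17 fell when adjusted over the list alone. All 24 measured ribosomal protein genes were negative as well, with a median of -0.60. Of these 5 fell over all genes tested and 19 when adjusted over the list alone, among them Rpl28 (-0.97), Rpl4 (-0.96), Rpl14 (-0.89) and Rps20 (-0.82). Camera gave both lists an adjusted p of 1.44e-08, against adjusted p = 0.761 with an estimated correlation for each. Both medians stayed negative after quantile normalization, at -0.29 and -0.28, where the lists passed with the preset correlation but not with an estimated correlation (adjusted p = 0.746 and adjusted p = 0.484). Not every member stayed negative there. The mitosis genes Plk1 (0.123) and Bub3 (0.075) and the ribosomal protein genes Rplp0 (0.051) and Rps27 (0.031) turned positive. Among 7 measured replication-dependent histone genes, the linker histone gene H1f2 fell from 1600 ± 55.4 to 763 ± 39.9 (-1.05 ± 0.08). Adjusted over the list alone 1 histone gene rose and 1 fell, and the list did not pass (median -0.41, camera adjusted p = 0.446; median -0.197 and adjusted p = 0.796 after quantile normalization).

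Neuronal genes moved in both directions. Of 40 measured pan-neuronal genes, 1 rose and 2 fell, over all genes tested and equally when adjusted over the list alone. Map2, a dendritic microtubule-associated protein gene, rose from 542 ± 41.5 to 777 ± 24 (0.51 ± 0.09, SE). The axonal Mapt fell from 2064 ± 78.7 to 1267 ± 136 (-0.70 ± 0.11, adjusted p = 0.0357, and 0.0699 after quantile normalization), as did Eno2, which also belongs to the glycolysis list. The list had a median of 0.06 and did not pass (camera adjusted p = 0.298). After quantile normalization the median was 0.22 and the list passed (camera adjusted p = 0.000421, and adjusted p = 0.484 with an estimated correlation), with 6 members higher and 1 lower. Of 21 measured sympathoadrenal and neuroblastoma lineage genes, the transcription factor genes Gata3 and Sox4 each rose by 0.87 and the neurotrophin receptor gene Ngfr fell by 1.12 on the log2 scale. After quantile normalization 4 of them were higher and 0 lower, with Ngfr at an adjusted p of 0.0523. Adjusted over the list alone 2 of these genes rose and 2 fell, and the list did not pass (median 0.135, camera adjusted p = 0.233; median 0.127 and adjusted p = 0.1195 after quantile normalization).

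Few genes tied to splicing and RNA decay passed the test on the values as deposited. Of 28 measured hosts of exons known to be regulated by PTB, the receptor gene Gabbr1 (0.60 ± 0.08, SE) and the transcription factor gene Mef2a (0.57 ± 0.11, adjusted p = 0.0492, and 0.0511 with each array centred on its median) rose and Hps1 fell (-0.85 ± 0.12, adjusted p = 0.0342, and 0.0566 after quantile normalization). Adjusted over the list alone 3 rose and 3 fell, and the list median was -0.045 (camera adjusted p = 0.754). After quantile normalization the median was 0.089, with 3 members higher and 0 lower (camera adjusted p = 0.178). None of the 24 measured tissue-restricted splicing regulators passed over all genes tested or adjusted over the list alone, with the largest differences in Celf2 (-0.80, adjusted p = 0.122) and Khdrbs2 (0.68, adjusted p = 0.173). Their median was 0.12 (camera adjusted p = 0.301). After quantile normalization 5 of these regulators were higher and 1 lower, Celf2 (adjusted p = 0.0442), with a list median of 0.17 that did not pass (camera adjusted p = 0.0665). Likewise none of 29 measured SR protein and hnRNP genes passed over all genes tested or adjusted over the list alone, and the widest differences were -0.53 for Hnrnpab and -0.46 for Hnrnpul1. Camera placed this list lower (median -0.22, adjusted p = 0.00512, and adjusted p = 0.761 with an estimated correlation). After quantile normalization its median was 0.07 and it did not pass (camera adjusted p = 0.587), nor did it without empty vector array 3 (adjusted p = 0.0966). Of 11 measured nonsense-mediated decay factors and targets, Gas5, a non-coding RNA degraded by that pathway, fell from 2560 ± 270 to 1716 ± 31.8 (-0.57 ± 0.10, adjusted p = 0.0439), over all genes tested and adjusted over the list alone. After quantile normalization Gas5 no longer passed (adjusted p = 0.156), and the list, with a median of -0.12 and 0.13 after it, did not pass in camera (adjusted p = 0.233 and 0.641). Among 13 measured genes of the REST repressor complex and small C-terminal domain phosphatases, the deacetylase gene Hdac1 fell from 2283 ± 178 to 1424 ± 113 (-0.67 ± 0.10), over all genes tested and adjusted over the list alone. A dimmer transcript cluster of Hdac1 gave -0.53 (adjusted p = 0.182), and the list did not pass (median -0.265, camera adjusted p = 0.315). After quantile normalization 2 members of this list were higher, Ehmt1 (0.44) and Kdm1a (0.61), and 1 was lower (median -0.074, camera adjusted p = 0.976).

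Cytoskeletal and stress response genes were mixed. Of 35 measured actin cytoskeleton and adhesion genes 5 fell and none rose over all genes tested, and 12 fell when adjusted over the list alone. Besides Anxa2, the tropomyosin gene Tpm4 fell from 5040 ± 618 to 2228 ± 368 (-1.18), the lamin gene Lmna fell by 0.98 on the log2 scale, and the intermediate filament gene Vim fell from 9378 ± 808 to 4811 ± 977 (-0.98, adjusted p = 0.0459, and 0.0593 after quantile normalization). The list median was -0.175 before and -0.12 after quantile normalization (camera adjusted p = 0.0062 and 0.0218, against adjusted p = 0.761 and adjusted p = 0.746 with an estimated correlation). Of 32 measured unfolded protein and amino acid stress response genes 3 fell, Pdia3, Sdf2l1 (-0.83) and Edem1 (-0.64), all acting in the endoplasmic reticulum, and 5 fell when adjusted over the list alone. That list's median was -0.25 (camera adjusted p = 0.0062, and adjusted p = 0.761 with an estimated correlation) and 0.085 after quantile normalization, where it did not pass (0.796), nor did it without empty vector array 2 (0.155). Among 25 measured immediate early genes Nr4a2 rose from 131 ± 17.3 to 239 ± 7.8 (0.80) and Ier3 fell, while 2 rose and 7 fell when adjusted over the list alone (median -0.18, camera adjusted p = 0.233). After quantile normalization 2 immediate early genes rose and 1 fell (camera adjusted p = 0.335). Of 25 measured interferon response genes Oasl2 rose from 98 ± 19.3 to 267 ± 43.7 (1.32 ± 0.18, SE), and 4 rose and 2 fell when adjusted over the list alone. After quantile normalization 2 interferon response genes were higher, Oasl2 and Ifit2 (0.97). The interferon list's median was -0.04 and its mean 0.115 (0.036 to 0.229 without any 1 array, but -0.256 without the dimmest 50% of clusters). The list did not pass in camera, whose direction was upward (adjusted p = 0.736) and turned downward after quantile normalization (median -0.152, adjusted p = 0.796). None of 21 measured p53 target genes passed over all genes tested or adjusted over the list alone, and Trp53inp1 (1.19, adjusted p = 0.115) and Cdkn1a (-0.62, adjusted p = 0.0601) differed most. The p53 list's median was -0.04 and its mean 0.05, between -0.036 and 0.089 without any 1 array (camera adjusted p = 0.865; median -0.031 and adjusted p = 0.796 after quantile normalization).

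**Figure D3:**
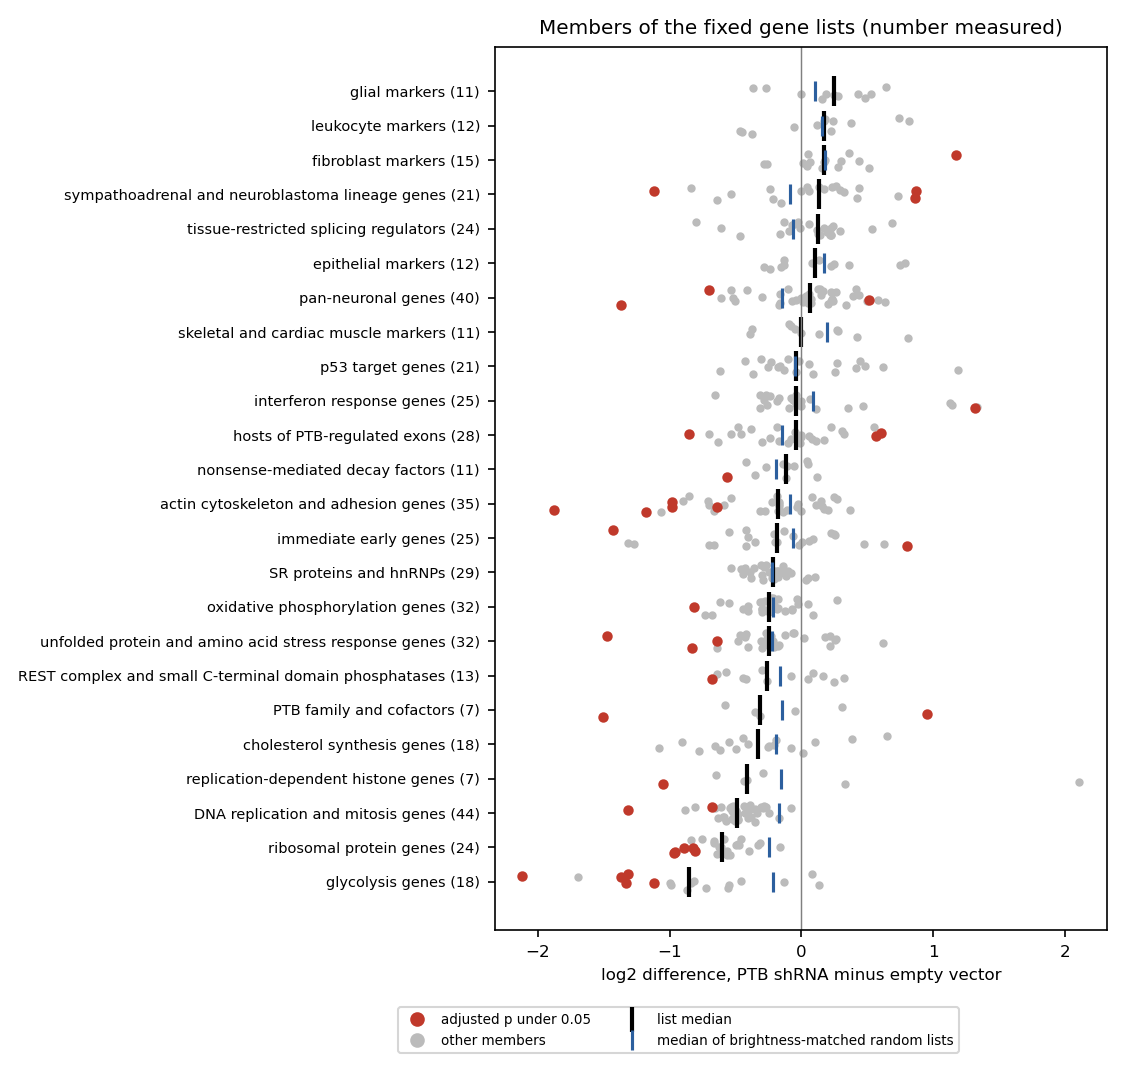
Log2 difference between PTB shRNA and empty vector (x axis) for each measured member of the 24 fixed gene lists (points, red where the adjusted p was under 0.05), with the list median in black and the median of 10000 random lists of like brightness in blue. Glycolysis, ribosomal protein and DNA replication and mitosis genes had the lowest medians, at -0.85, -0.60 and -0.49.

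Few markers of other cell types passed the test. Of 15 measured fibroblast markers the receptor gene Pdgfra rose from 36 ± 6.1 to 102 ± 21.5 (1.17 ± 0.17, SE), over all genes tested and adjusted over the list alone. The list did not pass (median 0.17, camera adjusted p = 0.0706, against adjusted p = 0.761 with an estimated correlation). With the preset correlation the list passed without empty vector array 1 (0.0439) or PTB shRNA array 3 (0.0173), but its mean of 0.21 fell to 0.09 without PTB shRNA array 1, and after quantile normalization its median was 0.006 (camera adjusted p = 0.796). None of the 11 glial, 12 leukocyte, 12 epithelial and 11 muscle markers measured passed over all genes tested or adjusted over the list alone. After quantile normalization the glial gene S100b (-0.49, adjusted p = 0.0484) and the leukocyte gene Cd14 (-0.66, adjusted p = 0.0457) were lower, and with each array centred on its median the leukocyte gene Aif1 was higher (0.76, adjusted p = 0.0409). The widest differences were in the leukocyte genes Tyrobp (0.81, adjusted p = 0.228) and Aif1 (0.74, adjusted p = 0.0735), the muscle genes Tnnc1 (0.81, adjusted p = 0.235) and Acta1 (0.42, adjusted p = 0.158), and the epithelial genes Cldn3 (0.79, adjusted p = 0.149) and Cldn7 (0.75, adjusted p = 0.112). Among glial genes they were Olig1 (0.64, adjusted p = 0.258) and Mog (0.53, adjusted p = 0.157). These sizes rest on single arrays and on the pseudocount. Leaving out 1 array brought Tyrobp down to 0.44, Tnnc1 to 0.50 and Olig1 to 0.37, and Cldn7 was at 2.19 with a pseudocount of 1 and 0.33 with 50. Medians were 0.24 for glial, 0.17 for leukocyte and 0.10 for epithelial markers, with camera adjusted p-values of 0.233, 0.274 and 0.233. After quantile normalization these medians were 0.148, 0.019 and -0.049, and camera's direction turned downward for leukocyte and epithelial markers (adjusted p = 0.796 for all 3 lists). The muscle list had a median of -0.003 and a mean of 0.08, between 0.0055 and 0.156 without any 1 array (camera adjusted p = 0.434), and a median of -0.178 after quantile normalization, with camera's direction downward (adjusted p = 0.581).

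Passing in camera did not always set a list apart from genes of like brightness. Among 10000 random lists of like brightness the medians of the glycolysis, ribosomal protein and DNA replication and mitosis lists lay at percentile 0 and that of the cholesterol list at percentile 5.18. The other called lists lay at percentile 11.19 (actin cytoskeleton and adhesion), 25.03 (oxidative phosphorylation), 28.96 (unfolded protein response) and 51.69 (SR proteins and hnRNPs). Of the lists not called, the pan-neuronal list lay at percentile 99.97, the sympathoadrenal list at 99.67 and the tissue-restricted splicing regulators at 99.44, and the others between 4.44 (muscle) and 93.89 (hosts of PTB-regulated exons). Such random lists leave out the correlation between genes.

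**Figure D4:**
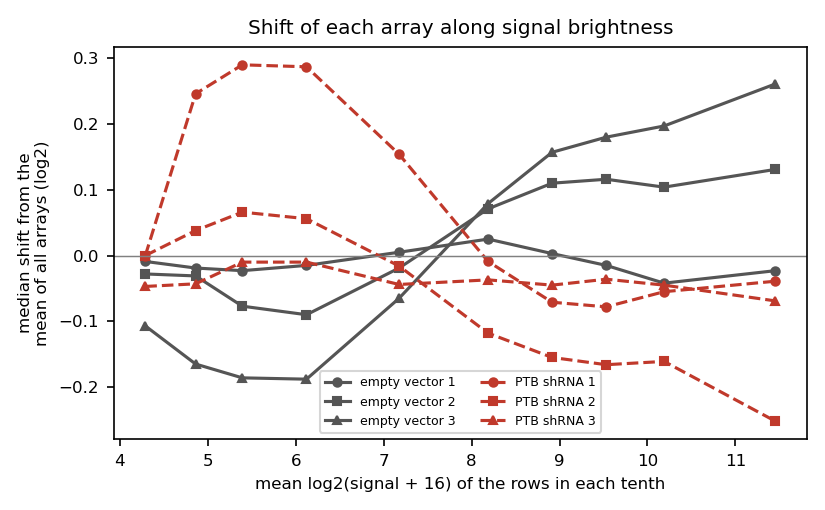
Median shift of each array from the mean of all 6 arrays (log2, y axis) within 10 equal bins of transcript clusters ordered by mean signal (x axis, log2 of signal plus 16). In the brightest bin the empty vector arrays lay at -0.02, 0.13 and 0.26 and the PTB shRNA arrays at -0.04, -0.25 and -0.07.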

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

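The brightness-matched random lists and the medians and estimated-correlation tests of single lists after quantile normalization were chosen after the data had been seen, and the other alternatives before. Ptbp1 stayed lower and Ptbp2 higher under every alternative run, while the counts of called transcript clusters, 234 higher and 580 lower in the main setting, moved with most of them. Quantile normalization gave 506 higher and 5 called lists in place of 8, and the means of the SR protein and hnRNP list and of the unfolded protein list turned positive, to 0.0279 and 0.0254. The means of 6 lists not called changed sign there too, 3 upward (hosts of PTB-regulated exons, nonsense-mediated decay, histones) and 3 downward (leukocyte, epithelial, muscle). Centring each array on its median gave 376 higher. A pseudocount of 1 gave 84 higher and 132 lower and ended the Ptbp1 call (-1.52, adjusted p = 0.0605), and a pseudocount of 50 gave 930 lower. Without the dimmest 30% of clusters there were 503 higher, 1429 lower and 6 called lists, with 3 of the 8 calls lost and 1 gained. Without the dimmest 50% there were 390 higher, 2145 lower and 5 called lists, and the median of the clusters kept was -0.18. The pan-neuronal mean turned to -0.0269, still above that median, and the list passed in camera, which compares it with other clusters (adjusted p = 0.0273). The means of the sympathoadrenal list (-0.0162) and the interferon list (-0.256) turned negative there too, without passing (camera adjusted p = 0.0827 and 0.567). Trend and robust settings gave 463 and 1502, and array weights 445 and 1180 with 7 called lists. With an estimated correlation 0 lists passed, and with fry 0, against 5 with an unadjusted fry p under 0.05. With the replicate number as a block limma called 0 higher and 0 lower (1708 and 2963 at an unadjusted threshold of 0.05), and Ptbp1 (-1.51) and Ptbp2 (0.96) both had an adjusted p of 0.084. Camera called 9 lists with that block. Same-numbered arrays correlated at 0.232, 0.055 and 0.258 in their deviations from the group means, and differently numbered ones at -0.263 to 0.05. Each empty vector array thus correlated best with its own number, for array 2 by little, so pairing by number stays open. The main fit has no block because no label says that a number marks a shared day. Leaving out any 1 array gave 0 higher and 0 lower each time, with the smallest adjusted p between 0.0536 and 0.112. Ptbp1 then ranged from -1.75 to -1.30, Ptbp2 from 0.90 to 1.03 and the number of called lists from 6 to 9. Both kinds of fit have fewer residual degrees of freedom, and the cause of the other changes was not tested. Of the 52 other named genes that had passed, 6 no longer did with quantile normalization, 2 with centring, 33 with a pseudocount of 1, and 52 with the block or any array left out, and none of the named genes turned direction. Of the 17 named genes that had not passed, 1 did with quantile normalization, 3 with centring, 2 with a pseudocount of 50, 2 with array weights and 5 with trend and robust settings. Without the dimmest 30% some of the 17 were left out, and of those kept 7 passed and 5 did not. Without the dimmest 50% more were left out, and the 7 kept all passed. Signal over background limits the dimmest clusters, where up to 7.02% of an array lay at or below 0.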

Other observations

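The tests of scaling, of single arrays, of bright genes, of culture conditions and of other splits for genes were chosen after the result was seen. The low-oxygen list was written after called genes had been seen, and the protocadherin family was picked because 4 of its members had been called. All genes in these paragraphs outside the named set were chosen that way.

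Genes known to respond to low oxygen were mostly lower with PTB shRNA. Of 44 measured members, 14 fell and none rose, 38 had a negative difference, and the median log2 difference was -0.77 (-0.505 after quantile normalization, with 10 members lower). Leaving aside the members of the glycolysis list, 29 remained, of which 9 fell, with a median of -0.46 (-0.35 after quantile normalization, with 5 lower). The 3 glycolysis genes outside the low-oxygen list, Pfkm (0.08), Ldhb (0.13) and Pkm (-0.46), had a median of 0.08 (-0.06 after quantile normalization), and none passed. Which genes were left over follows from a list written after called genes had been seen. They therefore do not show that the falls of glycolysis genes were confined to low-oxygen genes. The 9 include the angiogenic factor gene Vegfa, from 2554 ± 298 to 1424 ± 43.4 (SD, n = 3 arrays per group; -0.83), the collagen hydroxylase genes P4ha1 (-1.13) and P4ha2 (-0.93), and the glycogen synthase gene Gys1 (-1.10). The oxidoreductase gene Ero1a (-1.04), Ndrg1 (-1.40) and Fam162a (-1.33) fell too. The glucose transporter gene Slc2a1 (-1.70, adjusted p = 0.0587) did not pass, and 6 members had positive differences, none of which passed: Ppp1r3c (0.52, and 0.311 after quantile normalization), Cited2 (0.26), Pdk3 (0.186), Pfkfb4 (0.167), Car12 (0.06) and Wsb1 (0.04).

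The clustered protocadherin beta genes, neuronal cell-surface adhesion genes, lay higher with PTB shRNA. All 22 measured members had a positive difference, with a median of 0.73 (0.78 after quantile normalization). Pcdhb2, from 113 to 284 in mean signal (1.22 ± 0.10, SE), Pcdhb15 (1.17 ± 0.14), Pcdhb17 (0.97 ± 0.13) and Pcdhb21 (0.53 ± 0.10) rose. The 9 protocadherins outside the clusters had a median of 0.13 (-0.04 after quantile normalization). None of them passed, and after quantile normalization Pcdh15 was higher (1.00, adjusted p = 0.0467). Too few genes of the protocadherin alpha and gamma clusters had a transcript cluster with 1 gene symbol to be compared. The rise is therefore not shown to be particular to the beta genes.

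More transcript clusters were lower than higher with PTB shRNA. A single array as the only source is argued against. Without any 1 array at least 61% of the clusters under an unadjusted threshold of 0.05 were lower, against 66.6% with all arrays. Leaving out 1 array cannot speak to several arrays together. In the brightest 10% of clusters empty vector 3 (0.261) and PTB shRNA 2 (-0.252) were shifted most. Scaling between arrays that depends on brightness may account for the imbalance, since the share of called clusters that were lower went from 71.3% to 49.2% with quantile normalization. A true loss of bright transcripts through the knockdown would be removed by that normalization as well. In the brightest 10% of clusters the group shift had an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 can give, so the explanations cannot be told apart.

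For the low-oxygen genes, quantile normalization shows only that the shift with brightness is smaller than the falls of the called members. The list was written around called genes, and the median difference was only -0.24 in the brightest 10% of clusters. That outcome was thus largely fixed in advance and is no test of scaling. Quantile normalization brought random lists of like brightness to a median of 0.03, from -0.145, while the mean of all 44 members went from -0.732 ± 0.17 to -0.58 ± 0.148 (SE over arrays) and 10 of the 14 calls were left. A drop shared by the whole list stays open: of the 30 members not called, 22 (73.3%) were lower after quantile normalization, short of the share of over 75% set beforehand. Their median was -0.293 there and -0.408 on the values as deposited. A second condition set beforehand, on matched random lists, is not used, as the list was written around called genes. The share and the medians depend on the change itself, which decides who is left out, and members just short of the threshold such as Slc2a1 and Egln1 (-1.17, adjusted p = 0.0556) are among the 30. Denser or less oxygenated empty vector dishes could also give the pattern. The list mean was higher with empty vector in 9 of 9 pairs of arrays. A list written around falling genes gives that order almost by itself. The empty vector arrays differed among themselves in Aldoc (1693, 854 and 1552) and Ankrd37 (304, 159 and 376), less so in Slc16a3 (6968, 6898 and 8947). Empty vector 2 was also the lowest of them in Bhlhe40 (1474, 821 and 1527) and Eno2 (1178, 793 and 1311). Outside the list the same held for Anxa2 (689, 371 and 744) and Ier3 (1400, 952 and 1507). Among the 12 largest falls that array was not the lowest in Fbln2, Hmox1, Ptbp1, Gtdc1 and Rfwd3. The knockdown could give the falls too, and no label used here gives density or oxygen, so these explanations cannot be told apart.

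Random lists as bright as the protocadherin beta genes had a median of 0.009 on the values as deposited, against 0.73 for the family. Quantile normalization thus had little to remove and was no test of scaling by brightness. The family was also picked for its 4 called members. After quantile normalization the mean of all 22 members was 0.766 ± 0.16 (SE over arrays), from 0.759 ± 0.155, the same 4 were called higher, and random lists of like brightness had a median of -0.001. Signal shared between near-identical members may let few changed genes appear as many. The members' deviations from their group means correlated at 0.445 on average, percentile 100 of 1000 matched lists, whose median was 0.034. Genes regulated together would correlate too, so the number of separately changed members stays open, and an effect of the knockdown on them is a hypothesis.

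The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The grouping by label gave 814 called transcript clusters, a number reached by 1 of the 10 splits, and the highest of the others was 0 in limma, with 353 to 1811 clusters at an unadjusted threshold of 0.05. Each of the other splits puts arrays of both groups on each side, so a group difference widens the spread within sides. Their 0 therefore does not show what unrelated arrays would give. For gene lists the label grouping gave 8, a number reached by 2 of the 10 splits. The other splits gave from 0 to 10, and the 10 came with empty vector 1 and 3 and PTB shRNA 3 on the same side.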
